A study of Zea mays with 20 samples.

How the data were processed

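Leaves of 4 maize lines were sampled at 0, 1, 2, 4 and 7 days after 5-day-old seedlings had each received 1 mL of teliospores and were kept at 27 °C, per the labels' protocols. Total RNA (6 µg) was labelled and hybridised to Affymetrix maize arrays, 1 array per line and day, per the labels' protocols. Probe sets were summarised with MAS5, per the submitters' processing notes, which give no version and no detection calls. The values deposited by the authors are on a log2 scale, and this is read from the values, which run from 0 to 14.61: the antilog 2% trimmed mean of all probe sets was 500.1 to 500.2 on every array, so that the arrays had been scaled to a common trimmed mean. Between 2.13% and 4.21% of the probe sets of an array stood at a log2 value of 0. Unlogged signals and single probes were not used here.

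For 6 arrays the free-text description named another line or day than the title, the source name and the characteristics. These last fields matched one another on every array and were used. As a check, 250 probe sets had a gap of over 1.5 log2 units between 2 groups of arrays, and 156 of them split along the line labels. Most of these set Q319 against the rest (104 higher in the other 3 lines, 26 higher in Q319), so the labels of L282, L43 and Huangzao4 were checked less well. Without Q319, 146 probe sets had such a gap, and only 35 of them split along the line labels. The values therefore do little to check the labels of these 3 lines.

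The table held 17734 probe sets. The 113 Affymetrix control probe sets were left out, which gave 17621. Values below the 20th percentile of all values (log2 3.77) were raised to it as a floor, because low MAS5 signals have no reliable order. The 40% of probe sets with the lowest mean over all arrays were then left out, and 10572 were tested. A line at the floor on all days gives only a bound on a fold difference, written as "at least". Genes were named through the platform's table of probe sets and genes. It holds 1453 of the probe sets, of which 1452 have 1 gene and 1 has several, and the others are unnamed here. Of those tested, 956 had 1 gene, and 826 of them, for 699 genes, carried a name other than a locus number. The table gives symbols and synonyms without descriptions or positions for the array's sequences, so no coordinates are given. What a gene does is background knowledge.

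Linear models with a term for line and a term for day were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that followed an intensity trend, on 12 residual degrees of freedom. The line effect and the day effect were tested with moderated F statistics, and the 6 line pairs and the 4 days against day 0 with moderated contrasts, all two-sided. P-values were adjusted after Benjamini and Hochberg over the probe sets of each contrast, and an adjusted p under 0.05 counted as a call. The line-by-day trend added a slope over log2(day + 1) for each line, which left 9 residual degrees of freedom. As no line and day had a second array, the error of every test is what line and day leave over, which mixes array noise with true differences in course between lines. The number of seedlings behind an array is not given. The 4 day contrasts share the day 0 arrays, so no overlap between them was computed.

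Gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of the lists fixed before the data were examined, 24 had members on the array. A further 16 lists were added after the gene table had been read and array-wide summaries of the values had been seen, but before any comparison of lines or days. Lists with at least 5 probe sets tested entered the test, 10 fixed and 15 added, and p-values were adjusted within each family over all contrasts (100 and 150 tests). Lists of other tissues were among them: 0 of 4 pollen and anther probe sets, 0 of 14 seed storage probe sets 2 of 9 root probe sets, 3 of 22 endosperm and basal transfer cell probe sets and 11 of 47 MADS and homeobox probe sets passed the filter on signal, and of the last 6 were called for the line effect and 6 for the day effect. Named genes followed a rule fixed beforehand: genes with the largest range among line means or day means, genes that set 1 line apart from the other 3, the largest rises and falls on each day, the trend genes with the lowest p, and up to 4 members of each list with the lowest p of the line and of the day effect. The probe set with the highest mean stood for a gene. Where other probe sets of a gene had the opposite sign, as for aoc1, the gene was left out.

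The steps were tested on simulated data, normal noise around each probe set's real mean with its real residual SD. With 10572 probe sets, differences of 1 and 2 log2 units were recovered at 50% and 80% of the changed probe sets for L282 against Q319, and at 46% and 84% for day 7 against day 0, and 3.17% and 5.74% of the calls were false. The list test found 3 of 3 simulated shifts and called 1 of 247 other tests. The noise was drawn independently for each probe set. The simulation therefore cannot show how many list calls are false where the genes of a list vary together.

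Alternatives tried were quantile normalization, median centring, no floor or a floor at the 40th percentile, no filter or the lowest 60% left out, 1 probe set per gene, array weights, robust or untrended variances, an added 2-fold rule, fits without the day or line term or with only the 2 lines compared, other codings of time, camera on ranks, and leaving out each day, line and array. Leaving out the 3 Q319 arrays with the highest ef1a difference was added later. Other splits of the arrays were run for every count, and swaps of lines within days or of days within lines for each pair and day. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 under Python 3.11.15.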

Results

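Leaf RNA of 4 maize lines, L282, L43, Huangzao4 and Q319, was measured on Affymetrix arrays after seedlings had been inoculated with teliospores of Sporisorium reilianum, the smut fungus that causes head smut. Each line gave 1 array at 0, 1, 2, 4 and 7 days post inoculation (dpi), which makes 20 arrays, 5 per line and 4 per day. No line and day was repeated, so an SD given for a line is its spread over 5 days, and an SD for a day is its spread over 4 lines. No uninoculated seedlings of the later days were on arrays, so time after inoculation, seedling age and time in culture moved together. The labels do not say which lines resist the fungus. The series asks which genes differ between varieties at the stages of inoculation, in the search for candidates for head smut resistance. Median log2 signals of the arrays ranged from 7.25 to 7.65, and the number of arrays limits the precision of every comparison. Of the total variance of the 10572 probe sets tested, 37.7% lay between lines, 26.5% between days and 35.8% in what line and day left. The median shares per probe set were 20.9%, 27.5% and 38.5%. These shares are not adjusted for the number of groups, 5 days against 4 lines, and more groups take up more noise. They therefore do not rank day and line.

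Q319 stood furthest from the other lines. The transcript of pdc2, a pyruvate decarboxylase of fermentation, was at the floor on all 5 days in Q319 (3.77) and measured 7.31 ± 0.30 in Huangzao4, 7.40 ± 0.64 in L282 and 7.87 ± 0.54 in L43 (mean ± SD of log2 signal, n = 5 days). It was therefore at least 11.6-fold higher in Huangzao4, 12.4-fold in L282 and 17.3-fold in L43 (adjusted p = 2.30e-07, 1.61e-07 and 4.94e-08). Another fermentation gene, the alcohol dehydrogenase adh2, went the other way and was highest in Q319, at 10.32 ± 0.71 against 7.78 ± 0.63 to 8.37 ± 1.41 (5.84-fold over Huangzao4, adjusted p = 0.000177). The ribosomal protein gene rps21b measured 6.69 ± 0.56 in Q319 and 10.34 to 10.54 in the other lines, 12.6- to 14.5-fold lower. The ER chaperone gene bip1 was also lower, at 9.59 ± 0.62 against 11.10 to 11.34. All of these differences had the same sign on each of the 5 days. The 3' minus 5' difference of the ef1a control probe sets, a sign of RNA quality, was higher in the Q319 arrays of days 7, 4 and 1 (2.18, 1.83 and 1.69) than on any other array, with 0.89 to 1.62 in the other lines and 1.29 and 1.23 in the Q319 arrays of days 0 and 2. The actin difference was not raised on these arrays of days 7, 4 and 1, at 1.94, 1.82 and 2.36 (1.61 to 2.97 over all arrays). Without those 3 arrays the line effects of adh2 and bip1 were not called (adjusted p = 0.0917 and 0.0625).

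Genes higher in Q319 came from several processes. The xyloglucan endotransglycosylase gene xet1, which acts on cell walls, reached 12.30 ± 0.47 against 8.54 to 9.68 (L282 minus Q319 -3.76 in log2, 13.5-fold, SE 0.32, adjusted p = 4.68e-07). Cystathionine gamma-synthase cgs1, of methionine synthesis, was 6.06- to 7.99-fold higher, the superoxide dismutase gene Sod4A 5.00- to 5.34-fold, and prpo1 17.9- to 18.1-fold, all on 5 of 5 days. The iron-phytosiderophore transporter gene ys1 was 6.36- to 9.32-fold higher in Q319, and the glutathione S-transferase gene gst7 6.48- to 14.9-fold. The latter was higher than in L43 on 4 of the 5 days, and its line effect was lost without the arrays of day 0 or day 4 (adjusted p = 0.0692 and 0.0714). That of ys1 was lost without day 2 or day 4 (adjusted p = 0.0672 and 0.0978). Of the 10 jasmonate and oxylipin probe sets tested, 4 passed the line effect, also when adjusted over the list alone. Both probe sets of aoc1 are among the 4, with opposite signs for the same line pair (log2 differences of 1.30 and -1.37). The count therefore shows no common direction. Also among the 4, opr5, an oxophytodienoate reductase, was higher in Q319. The log2 differences of the other lines from Q319 were -1.49 to -1.74 for it. Allene oxide synthase aos1 was lower in Q319 than in L282 by 1.26. The line effect of aos1 was lost without day 7 (adjusted p = 0.0622). Without the Q319 arrays of days 1, 4 and 7, whose ef1a difference is given above, the line effects of ys1, gst7, opr5 and aos1 were not called (adjusted p = 0.0918, 0.215, 0.102 and 0.181).

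In limma, 2696 of the 10572 probe sets (25.5%) passed the line effect at an adjusted p under 0.05. Between L282 and Q319, 3112 probe sets were called, 1853 higher in L282 and 1259 lower. Between L43 and Q319, 2230 were called, 1268 higher in L43 and 962 lower. Between Huangzao4 and Q319, 2309 were called, 1253 higher in Huangzao4 and 1056 lower. Q319 was higher than each of the other 3 lines at 647 probe sets and lower than each at 917, and at 32 of the latter it was at the floor on every day. The line effect fell to 257 probe sets without Q319 and to 1628 without day 7. Without day 7 the L43 and Q319 count was 1482. Without the Q319 arrays of days 1, 4 and 7 the line effect had 1055 probe sets, and the pairs of L282, L43 and Huangzao4 with Q319 had 1378, 1053 and 1025.

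**Figure D1:**
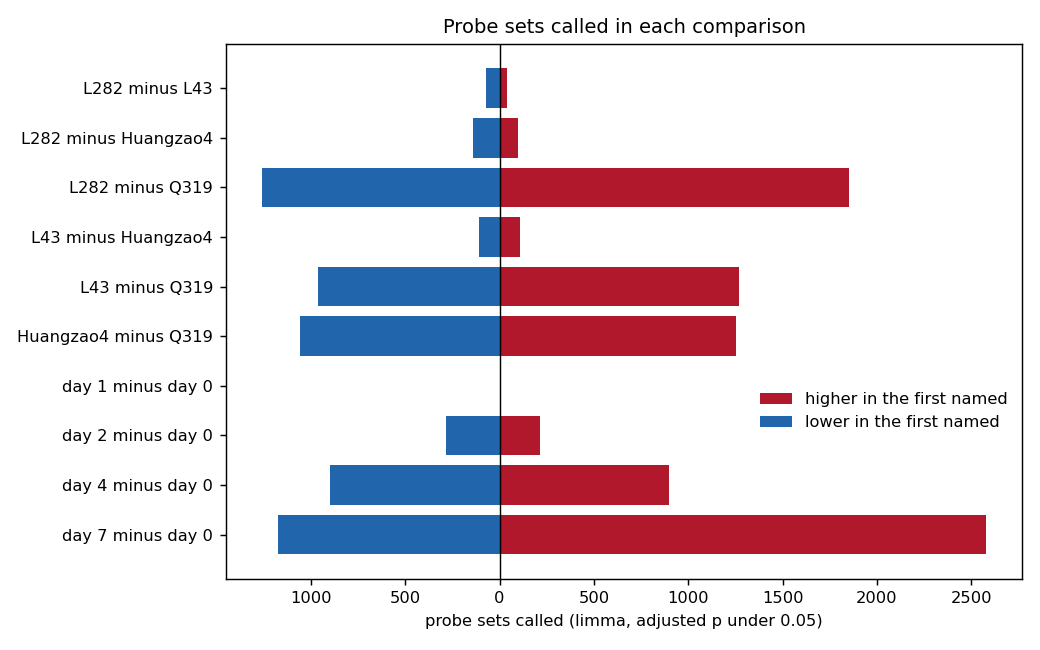
Number of probe sets called higher (right) or lower (left) in the first named line or day in each of 10 comparisons, limma, adjusted p under 0.05. The 3 pairs with Q319 hold 2230 to 3112 calls, the other 3 pairs 110 to 238, and the day comparisons rise from 0 on day 1 to 3752 on day 7.

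L282 differed from L43 and from Huangzao4 at fewer probe sets than from Q319. Among the genes called in both pairs, pgr5, needed for cyclic electron flow around photosystem I, measured 9.70 ± 1.47 in L282, against 12.01 ± 0.19 in L43 and 11.75 ± 0.43 in Huangzao4. It was 4.97-fold lower than in L43 (SE 0.40, adjusted p = 0.00845) and 4.13-fold lower than in Huangzao4 (adjusted p = 0.0120), in both cases on 4 of 5 days. The gene sat1 measured 5.87 ± 1.03 in L282 and 8.35 to 9.49 in the other lines, 5.77-fold below L43 and 5.57-fold below Huangzao4. On every day b3gat3 was lower as well, 4.89-fold against L43 and 4.33-fold against Huangzao4. Against Huangzao4, the plastid sigma factor gene sig1 was 4.40-fold lower in L282 and the nitrate reductase gene NNR1 4.19-fold lower, each on 5 of 5 days. The line effect of sig1 was lost without day 4 (adjusted p = 0.0574). The 2 genes were not called against L43, and whether L282 differed from these 2 lines by unequal amounts was not tested.

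For L282 against L43, 110 probe sets were called, 38 higher and 72 lower in L282. The count fell to 65, 69, 52 and 51 without days 1, 2, 4 and 7, to 53 without Huangzao4 in the fit, and to 71, 68 and 72 without the L43 arrays of days 2, 4 and 7. For L282 against Huangzao4, 238 were called, 97 higher and 141 lower, and this fell to 122, 128 and 114 without days 1, 4 and 7, to 155 without the day 7 array of L282 and to 151 without the day 1 array of Huangzao4.

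L43 and Huangzao4 differed by some large amounts. The gene prcw1 was expressed at 12.31 ± 0.56 in Huangzao4 and at 5.05 to 5.29 in the other lines, 153-fold above L43 (L43 minus Huangzao4 -7.26 in log2, SE 0.68, adjusted p = 6.62e-06) and 130-fold above Q319, on 5 of 5 days each. The auxin-binding protein gene abp4 was lower in Huangzao4 than in any other line, at 8.22 ± 0.17 against 10.04 ± 0.17 in L43 (3.51-fold, adjusted p = 4.43e-07). The gene umi11 was 5.91-fold higher in L43 than in Huangzao4 (adjusted p = 0.00338), on all 5 days. In this pair 214 probe sets were called, 106 higher in L43 and 108 lower, 71 and 77 of them by at least 2-fold. Single days differed: with no test, 2392 probe sets lay at least 2-fold apart on day 0 and 386 on day 1, whereas L282 and L43 had 479 on day 0 and 2226 on day 1.

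Among gene lists, the 13 probe sets of photosystem and light-harvesting proteins lay lower in L282 than in each other line over the 5 days together, but not on day 0 against L43 and Huangzao4. The list's median deviation on day 0 was 0.77 in L282, 0.50 in L43, 0.29 in Huangzao4 and 0.88 in Q319, and on day 4 -0.82 in L282 and -0.71 in L43. The median log2 difference over all days was -0.86 from L43, -1.17 from Huangzao4 and -1.63 from Q319 (camera, adjusted p = 1.29e-05, 8.47e-07 and 0.000161; adjusted p = 0.985 each with an estimated correlation). Against Q319, 8 of the 13 were called lower in L282 and 10 when adjusted over the list alone. They include psad1, of photosystem I (3.57-fold), and the light-harvesting gene lhcb5 (3.09-fold), whose line effect was lost under median centring (adjusted p = 0.0531) and without a filter (adjusted p = 0.0795). Neither gene was called without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.223 and 0.196) or without day 4 (adjusted p = 0.111 and 0.204). Against L43 and Huangzao4, 1 of the 13 was called in each pair. No single array left out ended the 3 list calls, but without the day 7 array of L282 the medians were -0.23, -0.55 and -1.01. The 25 aquaporin probe sets were lower in L282 than in L43, Huangzao4 and Q319 by medians of -0.23, -0.55 and -0.42 (adjusted p = 0.00793, 0.00239 and 0.0394; 0.985 each as adjusted p with an estimated correlation), with the list median lower on 3, 4 and 4 of the 5 days. Against Q319 they were mixed, with 10 called lower and 3 higher, and the list was not called after quantile normalization (adjusted p = 0.0719), with 1 probe set per gene (0.366) or without the Q319 arrays of days 1, 4 and 7 (0.412). The 26 probe sets of ER folding proteins were higher in L282 than in L43 (median 0.16, adjusted p = 0.0321) and Q319 (median 0.32, adjusted p = 0.0332), with 8 members called higher and 1 lower in the second pair (adjusted p = 0.985 each with an estimated correlation), and with the list median higher on 3 and 5 of the 5 days. With 1 probe set per gene these adjusted p-values were 0.0669 and 0.0614, and without the day 1 array of L282 0.473 and 0.0852. The second was 0.195 without the Q319 arrays of days 1, 4 and 7. The first call was also lost without the L43 array of day 1 or 2 (adjusted p = 0.0764 and 0.436), and the second without the Q319 array of day 0 or 1 (adjusted p = 0.0722 and 0.0832). Cell wall and expansin genes (12 probe sets) were lower in L43 than in Huangzao4 by a median of -0.63, with none called singly (adjusted p = 0.0462; adjusted p = 0.98 with an estimated correlation). Cellulose synthases (13) followed with -0.57 (adjusted p = 0.0193), and 45 ribosomal and translation factor probe sets were lower in L282 than in Huangzao4 by -0.15 (adjusted p = 0.0321), on 3 of 5 days. Both had an adjusted p of 0.985 with an estimated correlation. After quantile normalization the cell wall and ribosomal lists were not called (adjusted p = 0.108 and 0.142), nor was the latter with 1 probe set per gene (adjusted p = 0.258). The aquaporin calls ended without the day 7 array of L282 (adjusted p = 0.265, 0.0544 and 0.101), and the cell wall, cellulose synthase and ribosomal calls without any 1 of 8, 6 and 5 arrays (highest adjusted p = 0.671 and 0.526 without the day 2 array of L43 and 0.589 without the day 0 array of Huangzao4). All 29 list calls of the line and day comparisons, 5 of lists fixed before the data were examined and 24 of lists added after the gene table was read, were lost with an estimated correlation.

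By day 7 after inoculation, genes known from senescing leaves and several metabolic genes had risen in all 4 lines. Malate synthase mas1, of the glyoxylate cycle, rose from 5.87 on day 0 to 11.27 on day 7 (log2 difference 5.40, 42.1-fold, SE 0.81, adjusted p = 0.000569, 4 of 4 lines). The legumain-like protease gene see2b, known from senescing leaves, rose 4.82-fold (SE 0.33, adjusted p = 0.000483) and its relative see2a 2.03-fold. Pheophorbide a oxygenase lls1, of chlorophyll breakdown, rose 8.57-fold (adjusted p = 0.00171), and the ACC oxidase gene acco20, of ethylene synthesis, 11-fold (adjusted p = 0.00188). The MADS-box genes m26, zmm19 and m20 rose 15.3-fold, 13.2-fold and by 2.09 log2 units. They belong to a list of MADS and homeobox genes known from other tissues, of which 5 of the 11 tested were called higher on day 7 and 1 lower, and which was not called as a list (median 0.43, adjusted p = 0.511). Between days 0 and 7 the median deviation of this list went from -0.25 to 0.70 in L282, -0.19 to 0.02 in L43, 0.02 to 0.31 in Huangzao4 and -0.72 to 0.60 in Q319. Higher on day 7 were also sucrose synthase sh1 (3.94-fold, adjusted p = 0.000199), the glutamine synthetase gene gln5 (3.80-fold), the glutathione S-transferase gene GST39 (6.17-fold) and the cyclin gene cycD2 (2.91-fold). Each of these genes went up in 4 of 4 lines. The day effect of see2a was lost under median centring (adjusted p = 0.105), and those of see2a, lls1 and m26 without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.0594, 0.0526 and 0.0522). Leaving out 1 line ended the day effect of each of these genes but sh1 and gln5. Without L43 the adjusted p was 0.163 for acco20, 0.136 for GST39, 0.0811 for zmm19, 0.0752 for lls1, 0.0552 for mas1 and 0.0517 for see2b. It was 0.089 for see2a without Huangzao4. Without L282 it was 0.114 for m26. Without Q319 it was 0.102 for cycD2 and 0.0524 for m20.

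Several of the named genes that fell by day 7 act in the chloroplast. The plastid 2-oxoglutarate/malate transporter pOMT1 fell from 12.36 to 9.34 (log2 difference -3.02, 8.12-fold, SE 0.32, adjusted p = 0.000201) and the dicarboxylate transporter pDCT2 from 12.66 to 9.85 (-2.80). Phytoene synthase psy2 and oy1, a magnesium chelatase subunit, fell by log2 differences of -2.11 and -1.86. They belong to the chlorophyll and carotenoid list of 4 probe sets, too small for the list test, of which 3 passed the day effect, the third being the desaturase gene pds1 (adjusted p = 0.0391; 0.0639 after quantile normalization), while vp9 had an adjusted p of 0.069. Ferredoxin-thioredoxin reductase ftr1 (-2.07), leaf ferredoxin-NADP reductase L-FNRI (-1.65) and the desaturase gene FAD8 (-2.44) fell too. A steeper fall was that of amy5, from 10.89 to 4.89 (63.9-fold, SE 1.14, adjusted p = 0.00186). The expansin gene EXPA5 fell 8.14-fold, the glutamine synthetase gene gln1 6.69-fold, the thiazole synthesis genes thi1 and thi2 4.25- and 3.76-fold, and the aquaporin genes tip2a and tip2b 5.89- and 4.82-fold. Sucrose-phosphate synthase sps1 fell 8.52-fold, though its day effect was lost after quantile normalization (adjusted p = 0.0564) and without a filter (adjusted p = 0.0828). Apart from pds1 and vp9, which were not examined by line, all of these were lower on day 7 in every one of the 4 lines. The day effects of tip2a, tip2b and pds1 were lost without a filter (adjusted p = 0.0511, 0.0578 and 0.0643), and that of tip2b with a floor at the 40th percentile (adjusted p = 0.165). Those of tip2a, tip2b, oy1, EXPA5, thi2 and pds1 were lost without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.0877, 0.105, 0.0969, 0.0984, 0.106 and 0.139). Leaving out 1 line ended the day effect of each called gene of this paragraph but pOMT1, ftr1 and thi1. Without L43 the adjusted p was 0.228 for sps1, 0.223 for EXPA5, 0.0661 for pDCT2, 0.0659 for FAD8 and 0.061 for L-FNRI. Without Huangzao4 it was 0.199 for tip2a, 0.0922 for thi2 and 0.0567 for psy2. Without Q319 it was 0.219 for pds1, 0.173 for oy1, 0.129 for tip2b, 0.0883 for amy5 and 0.0813 for gln1.

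The day effect was called at 2237 of 10572 probe sets (21.2%). On day 7, 3752 were called against day 0, 2580 higher (68.8%) and 1172 lower. On day 4, 1795 were called, 898 higher and 897 lower. The median of all probe sets shifted by 0.12, 0.17 and 0.22 on days 2, 4 and 7 as deposited, by 0.01, 0.05 and 0.06 after quantile normalization and by -0.10, -0.10 and -0.03 after median centring, and the changes of single genes given above include that shift. The splits moved with it. After quantile normalization there were 1448 higher and 1260 lower on day 7 and 497 and 1023 on day 4, and after median centring 840 and 1621 on day 7 and 205 and 1345 on day 4. The day effect fell to 205 probe sets without L43, 545 without Huangzao4, 586 without Q319, 580 without day 7, 1402 without the day 7 array of L282 and 969 without the Q319 arrays of days 1, 4 and 7, which left 1034 calls on day 4 and 2495 on day 7. The day 7 count fell to 2370, 2170 and 2316 without L43, Huangzao4 and Q319. On day 4 it fell to 334, 1026 and 797 without these lines, to 981 and 1114 without the day 0 arrays of L282 and L43, and to 811, 1104 and 1110 without the day 4 arrays of L43, Huangzao4 and Q319.

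The lists follow these genes. Of the 11 senescence-associated probe sets, 8 rose by day 7 and 9 when adjusted over the list alone, and none fell. The list's median log2 change was 0.67, 0.88 and 1.20 on days 2, 4 and 7, against the shifts of all probe sets given above (adjusted p = 0.0204, 0.0204 and 0.0224; adjusted p = 0.985 each with an estimated correlation). It was lost on each of these days without the day 0 array of Huangzao4 (adjusted p = 0.220, 0.159 and 0.0990), on day 4 also without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.0635), and on day 2 also without the day 2 arrays of L43 and Huangzao4 (adjusted p = 0.0759 and 0.172). Of the 11 probe sets of carbon fixation and C4 enzymes, 7 fell by day 7, among them phosphoenolpyruvate carboxylase pep1 (-1.54), the chloroplast glyceraldehyde-3-phosphate dehydrogenase gpa1 (-1.28), NADP-malic enzyme me3 (-1.10) and NADP-malate dehydrogenase mdh6 (-1.05), each in 4 of 4 lines. The day effects of pep1 and me3 were lost after quantile normalization (adjusted p = 0.108 and 0.11) and without a filter (adjusted p = 0.0828 and 0.0623). Those of pep1, gpa1, me3 and mdh6 were lost without L43 (adjusted p = 0.267, 0.132, 0.258 and 0.163). The 1 that rose was 1 of 4 probe sets of pdk1, pyruvate orthophosphate dikinase, singled out after its values were seen, and the other 3 had negative values. The list median was -0.37, -0.58 and -0.56 on days 2, 4 and 7 (adjusted p = 0.0378, 0.00504 and 0.00504; adjusted p = 0.98 each with an estimated correlation). It was not called after quantile normalization on any of them (adjusted p = 0.890, 0.312 and 0.222), nor on day 2 after median centring (adjusted p = 0.0658), and on day 2 its median deviation was 0.35 higher in Huangzao4 and lower in the other 3 lines. The day 2 call was also lost without the L282 array of day 0, 1 or 2 (adjusted p = 0.206, 0.0587 and 0.0962), the L43 array of day 0 or 2 (0.0816 and 0.0535) or the Q319 array of day 2 (0.118). Photosystem and light-harvesting proteins showed medians of -0.60, -0.81 and -1.14 (adjusted p = 0.00139, 0.00101 and 8.73e-05; adjusted p = 0.985 each with an estimated correlation), and 7 of 13 fell by day 7. After quantile normalization the list was called on day 7 but not on days 2 and 4 (adjusted p = 0.127 and 0.0982), and the day 2 call was lost without the day 0 array of L282 (adjusted p = 0.0515) and in Huangzao4 its median did not move by day 2. In L282 its median deviation went from 0.77 on day 0 to -3.14 on day 7, and in Q319 from 0.88 to 0.56.

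**Figure D2:**
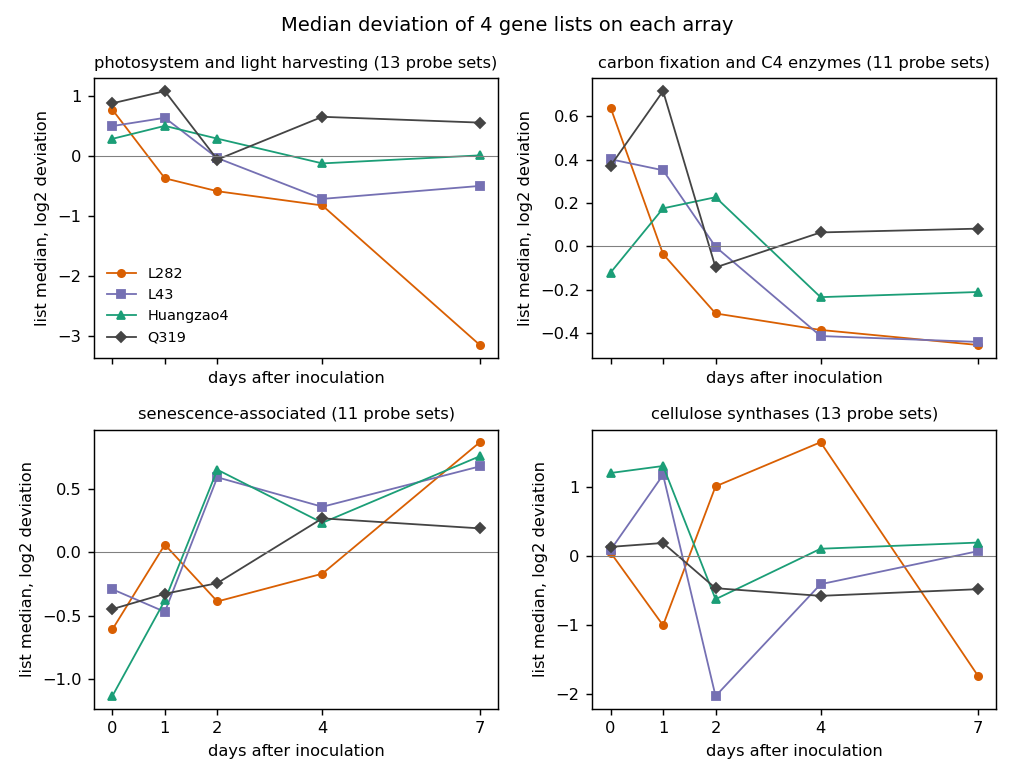
Median log2 deviation of 4 gene lists from each probe set's mean over the 20 arrays, against days after inoculation, 1 line per maize line and 1 point per array. The photosystem list reached -3.14 in L282 on day 7, the senescence list was below 0 on day 0 in all 4 lines, and the cellulose synthase list spanned -2.02 to 1.65.

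ER folding proteins rose on days 2 and 4 by medians of 0.60 and 0.57 (adjusted p = 0.000129 and 0.00563; adjusted p = 0.985 each with an estimated correlation), with 4 and 6 of 26 probe sets called higher and 13 on either day when adjusted over the list alone. Glycolysis and fermentation genes (17) were lower on day 7 with a median of -0.57 (adjusted p = 0.0429; adjusted p = 0.985 with an estimated correlation), 4 called lower, among them enolase eno1 (-0.94) and glucose-6-phosphate isomerase phi1 (-1.58), and 1 higher, adh2 (1.77). The list was not called after quantile normalization (adjusted p = 0.365), median centring (0.117), with 1 probe set per gene (0.214) or on ranks (0.0525). Its median deviation between days 0 and 7 went down in L43 (0.18 to -0.12) and Huangzao4 (0.10 to -0.37) and up in L282 (-0.58 to -0.25) and Q319 (-0.48 to -0.28). The day effects of eno1 and adh2 were lost after quantile normalization (adjusted p = 0.098 and 0.0573), and that of adh2 also under median centring (0.071), without a filter (0.0571) and without the Q319 arrays of days 1, 4 and 7 (0.137). Without L43 the day effects of eno1, phi1 and adh2 were not called (adjusted p = 0.081, 0.0623 and 0.202). Cellulose synthases were lower on days 2 and 7 by -0.69 and -0.84 (adjusted p = 0.0253 and 0.0321; adjusted p = 0.985 each with an estimated correlation) with no member called. On day 2 L282 went the other way, with a median deviation from 0.05 to 1.01, and between days 0 and 7 that of L43 went from 0.09 to 0.07. These calls were not kept after quantile normalization (adjusted p = 0.0847 on each day) or median centring (0.113 and 0.104), nor that of day 7 without the Q319 arrays of days 1, 4 and 7 (0.0642). Chromatin proteins (58) were higher on day 2 by 0.31 (adjusted p = 0.00793), and 45 ribosomal and translation factor probe sets lower on day 7 by -0.17 (adjusted p = 0.0429), both with an adjusted p of 0.985 with an estimated correlation. The ribosomal median deviation between days 0 and 7 went down in Huangzao4 (0.44 to -0.18) and Q319 (0.16 to -0.16) and up in L282 (-0.47 to -0.07) and L43 (-0.28 to -0.20). The ribosomal call was lost after quantile normalization (adjusted p = 0.923) and without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.244). No single array ended the 2 ER folding calls, whereas any 1 of 6 arrays ended the glycolysis call and any 1 of 7 the ribosomal call (highest adjusted p = 0.0990 and 0.465, both without the day 0 array of Huangzao4). The chromatin call ended without the day 2 array of Q319 (adjusted p = 0.176), and the cellulose synthase calls without the day 2 array of L43 (0.473) and the day 7 array of L282 (0.20), among others.

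**Figure D3:**
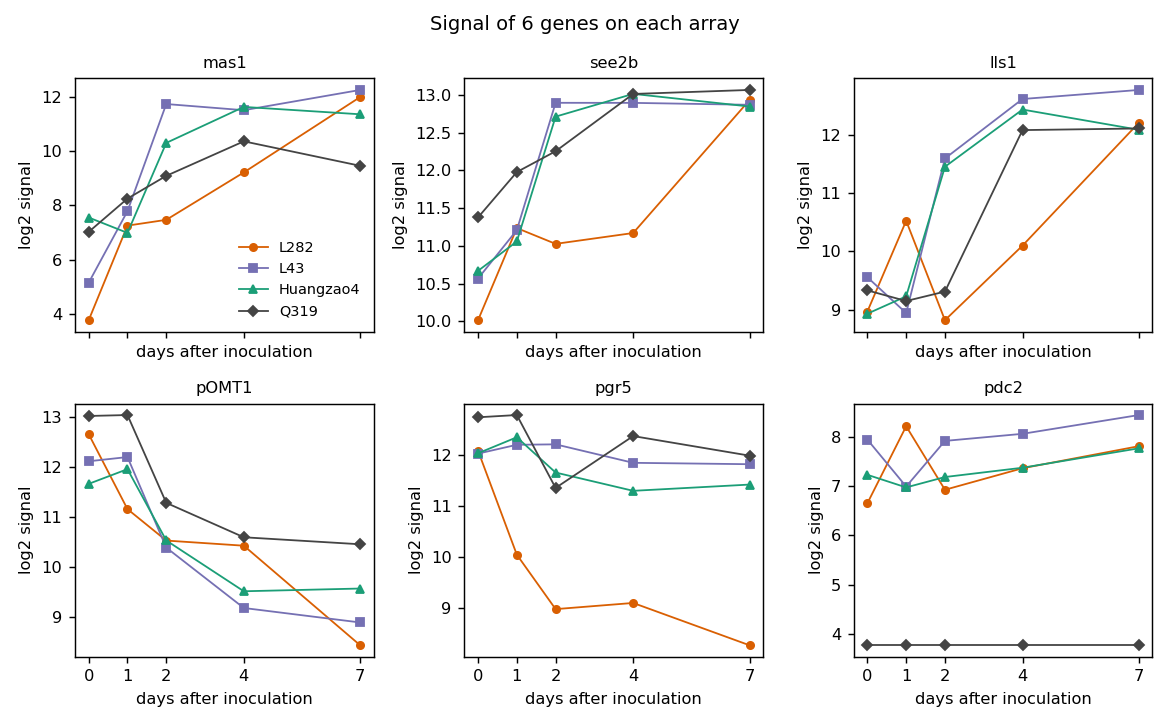
Log2 signal of mas1, see2b, lls1, pOMT1, pgr5 and pdc2 on each of the 20 arrays against days after inoculation, 1 line per maize line. mas1, see2b and lls1 were higher and pOMT1 lower on day 7 than on day 0 in all 4 lines, pgr5 was lowest in L282, and pdc2 lay at the floor of 3.77 on all 5 days in Q319.

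On day 1 no single probe set passed limma's test against day 0 (0 called, 134 at an unadjusted p under 0.05). Glutathione S-transferases, detoxifying enzymes, were the 1 group called. The list fixed before the data were examined (8 probe sets, with glucosyltransferases) had a median log2 change of 0.54 (adjusted p = 0.0227; adjusted p = 0.98 with an estimated correlation), and the added list of 27 probe sets 0.54 (adjusted p = 0.00493; adjusted p = 0.985 with an estimated correlation). The lines differed: between days 0 and 1 the median deviation of the fixed list went from -1.07 to 0.41 in L282 and from -0.35 to 0.40 in Q319, but from -0.14 to -0.39 in L43 and from -0.08 to -0.10 in Huangzao4. That of the added list went from -0.91 to 0.13, -0.30 to 0.08, -0.26 to -0.57 and -0.66 to -0.26 in the same order. The fixed list was not called without the day 0 or day 1 array of L282 (adjusted p = 0.452 and 0.199) or of Q319 (adjusted p = 0.0955 and 0.198). The added list was not called without the day 0 or day 1 array of L282 (adjusted p = 0.367 and 0.163) or without the day 1 array of Q319 (adjusted p = 0.0563).

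On day 2, mas1 rose 13.7-fold (adjusted p = 0.0288), see2b 2.96-fold (adjusted p = 0.0267) and sh1 2.78-fold (adjusted p = 0.0137), each in 4 of 4 lines, while amy5 fell 25.6-fold (adjusted p = 0.0382), pOMT1 3.20-fold (adjusted p = 0.0258) and psy2 3.24-fold (adjusted p = 0.0324). In all 499 probe sets were called, 214 higher and 285 lower, with 67 and 164 after quantile normalization and 77 and 605 after median centring. The count rested on single arrays: it was 0 without the day 0 array of L282, 1 without that of L43, 4 without the day 2 array of Huangzao4, 45 without that of Q319, 66 without the day 0 array of Q319, 202 without the day 2 array of L43, 222, 231 and 236 without those of Huangzao4 on days 4, 7 and 1, 278 without the day 4 array of Q319, 280 without the day 7 array of L43, 894 without the day 0 array of Huangzao4 and 1001 without the day 1 array of L282. It was also 0 without L43, 21 without Huangzao4, 10 without Q319, 290 without day 4, 26 without day 7 and 48 without the Q319 arrays of days 1, 4 and 7.

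Whether lines took different courses was tested as a line-by-day trend over log2 of day plus 1. limma called 2 probe sets of 10572 (579 at an unadjusted p under 0.05), and neither has a gene in the table used here. The first went from 10.33 to 5.72 in L282 and from 9.75 to 10.89 in Q319 between days 0 and 7 (adjusted p = 0.0438). The second went from 6.33 to 9.56 in Q319 and from 7.87 to 5.80 in L282 (adjusted p = 0.0438). Among named genes psad1 came closest without being called (unadjusted p = 0.00115 in limma), and adjusted over the list alone 6 of 13 photosystem and light-harvesting probe sets and 3 of 3 of the light reaction list passed. The count was 0 or 1 after leaving out any single array or line, and 0 without days 0, 1, 4 or 7 or without the Q319 arrays of days 1, 4 and 7.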

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

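The tests of the day 7 array and of RNA breakdown in this part were chosen only after the result was seen. The 2 probe sets called in the line-by-day trend were picked out because lines differed in course: the first went down in L282, from 10.33 to 5.72, and the second went up in Q319, from 6.33 to 9.56 (limma, adjusted p = 0.0438 each). Of 100 reassignments of what line and day left over, 1 reached 2 calls, the real one, and the highest other gave 1. Counts of 2 against 1 are too small to exclude chance. Most single arrays left out brought the count to 0.

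Photosystem and light-harvesting genes lay lower in L282 than in each other line over all days, though not on day 0 against L43 and Huangzao4, with median deviations of 0.77 in L282, 0.50 in L43 and 0.29 in Huangzao4. Against the day 7 array of L282 as the sole cause, the list stayed called lower in 3 of 3 pairs without it, with medians of -0.23, -0.55 and -1.01 (adjusted p = 0.0180, 2.91e-05 and 0.000163 in camera). The size did depend on that array, since the medians with it were -0.86, -1.17 and -1.63. On RNA breakdown in that array the controls do not decide. Its ef1a 3' minus 5' difference was exceeded on 8 other arrays. Its actin 3' minus 5' difference (2.97) was the highest of all arrays, just above that of the day 1 array of L43 (2.96). Its actin 3' signal (log2 5.51) was the lowest. With these values its actin 5' signal lay below the floor of 3.77, where signals have no reliable order. Its actin difference is therefore no reliable sign of breakdown. Its share of probe sets at a log2 value of 0 (4.21%) was also the highest. RNA breakdown there therefore cannot be told apart. A difference in course between the lines may account for the lower list in L282 (6 of 13 passed the trend test adjusted over the list alone). How far seedlings of L282 had declined by day 7 may do so too, which was not tested. All 3 list calls were lost with an estimated correlation (adjusted p = 0.985 in camera).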

How the results depend on the processing

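Chosen after the data were seen were leaving out single arrays or the Q319 arrays of days 1, 4 and 7 and, for the gene lists, median centring. No list call turned its direction under any setting, and no line or day effect of a named gene did. For named genes only the highest and the lowest line or day of the main fit were compared, so a turn was unlikely from the start. No direction was compared for the trend genes. The balance of calls did turn: median centring turned 2580 higher and 1172 lower on day 7 into 840 and 1621, and 1253 and 1056 for Huangzao4 against Q319 into 1058 and 1066. Changes of counts beyond 1.5 times were as follows, and the cause was not tested except where fewer arrays or probe sets entered by construction. Quantile normalization gave 231 calls on day 2, 0 trend calls and 1 call of the fixed lists. Median centring gave 1457 for the day effect and 2461 on day 7. A floor at the 40th percentile gave 0 trend calls. Without a filter, L43 against Huangzao4 had 347 calls and day 2 had 146. With the lowest 60% left out, so with fewer probe sets, the line effect had 1570, the pairs L282 with L43, Huangzao4 and Q319 57, 125 and 1865, L43 with Huangzao4 and Q319 103 and 1260, Huangzao4 with Q319 1281, and the trend 1. Array weights gave 6203 for the day effect, 417 for L282 against Huangzao4, 443 and 3396 for L43 against Huangzao4 and Q319, 4055 for Huangzao4 against Q319, 1812 and 4053 on days 2 and 4, and 7 trend calls. An added 2-fold rule, stricter by construction, gave 1590 and 1287 for the line and day effects, 156 and 1466 for L282 against Huangzao4 and Q319, 1113 for L43 against Q319, 1188 for Huangzao4 against Q319, and 295, 920 and 1569 on days 2, 4 and 7. Without the day term, L282 against L43 and Huangzao4 gave 71 and 155, and with only the 2 lines in the fit 31 and 60. Without the line term, the day effect gave 1261 and days 2, 4 and 7 gave 19, 1010 and 2439. A linear trend in log2(day + 1) gave 4719 for the day effect. A contrast of later days with day 0 by line, and a trend in unlogged day, gave 0 and 0 line-by-day calls. Without the Q319 arrays of days 1, 4 and 7, so with fewer arrays, the line and day effects had 1055 and 969, L282, L43 and Huangzao4 against Q319 1378, 1053 and 1025, days 2, 4 and 7 48, 1034 and 2495, and the trend 0. Camera with an estimated correlation gave 0 calls of the fixed and 0 of the added lists.

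Leaving out 1 day, line or array, counts ranged from 257 to 2911 (line effect), 205 to 3122 (day effect), 51 to 140 (L282 against L43), 114 to 287 (L282 against Huangzao4), 1482 to 2423 (L43 against Q319), 0 to 1 (day 1), 0 to 1001 (day 2), 334 to 2133 (day 4), 2170 to 4160 (day 7), 0 to 2 (trend) and 3 to 10 (fixed lists). Where a line or day had 1 array fewer, the spread was taken from all lines and days. Of 77 named genes with a day effect, 29 lost it after quantile normalization and 24 after median centring, and of 71 with a line effect, 1 and 4. Without day 0, 14 of the 71 were lost, and without the Q319 arrays of days 1, 4 and 7, 40 of the 71 and 41 of the 77. Without a filter 24 of the 77 were lost, and without the line term 31. With 1 line left out, so with fewer arrays, day effects of named genes were lost 205 times and kept 103 times, and line effects 6 and 136 times. With 1 day left out the numbers were 54 and 177, and 89 and 266. The day and line terms compare lines within days and days within lines; beyond that, no paired analysis was possible because the labels give no replicate numbers. Signal over background limits lines at the floor to bounds.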

Other observations

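The tests of probe sequence and signal scale in Q319, of swaps within days and lines and of RNA breakdown in this part were chosen only after the result was seen. Further genes set Q319 apart. The chromatin genes hac108, a histone acetyltransferase, and hda102, a histone deacetylase, were both higher in Q319 than in any other line (log2 differences of the other lines from Q319 of -1.51 to -1.66 and -0.76 to -0.95), and so was ohp1, known as a bZIP factor (-1.53 to -1.83). The homeobox gene ocl3 was lower in Q319, by 2.31 against L282, and so were the cytokinin receptor gene HK1, by 1.36 to 1.73, and the receptor kinase gene serk1, by 0.97 to 1.03, the last with its line effect lost after quantile normalization (adjusted p = 0.0737) or without day 0, 2 or 7 (adjusted p = 0.0881, 0.0728 and 0.0848). The catalase gene cat1 was lower there by 0.95 to 1.13. A second probe set of cat1 differed in the same direction by 0.66 where the first differed by 1.13, and did not pass the line effect (limma, adjusted p = 0.176). In the benzoxazinoid list, igl1, an indole-forming lyase, was higher in Q319 (-0.76 to -1.22), and glu2 was lower (1.37 to 1.60), although its line effect was lost without any 1 of days 0, 1, 2 and 4 (adjusted p = 0.0783, 0.0873, 0.0959 and 0.0775). Without the Q319 arrays of days 1, 4 and 7 the line effects of hda102, HK1, serk1 and glu2 were not called (adjusted p = 0.0685, 0.0719, 0.166 and 0.0698).

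Several defence groups showed no calls, which does not show that they were unchanged. Their members were found by gene symbol and synonym alone, and the gene table holds only 1453 of the 17734 probe sets. In the simulation, differences of 1 log2 unit were recovered at 46% of the changed probe sets for day 7 against day 0 and at 50% for L282 against Q319. Recovery by the tests of the line and day effects was not measured. None of the 5 probe sets of pathogenesis-related proteins passed the line or the day effect in limma, nor did those of terpenoid synthesis (3), heat shock proteins (3) and phenylpropanoid and lignin synthesis (2). Of 20 tubulin and actin-binding and 13 cellulose synthase probe sets, 0 passed either effect, also when adjusted over the list alone. At an unadjusted p under 0.05 in limma these 6 lists held 1 probe set for the line effect, from the heat shock list, and 0 for the day effect. Of 11 peroxidase and antioxidant probe sets, 4 passed the line effect and 4 the day effect (5 and 8 adjusted over the list alone). At day 7 the glutathione reductase gene gor1 was lower (-0.89) and the ascorbate peroxidase gene apx2 higher (0.74), though the day effect of apx2 was lost under median centring (adjusted p = 0.327) and those of gor1 and apx2 without the Q319 arrays of days 1, 4 and 7 (adjusted p = 0.0689 and 0.22) and without L43 (adjusted p = 0.122 and 0.22). Of 9 nitrogen assimilation probe sets 3 passed each effect, and of 9 starch and sucrose probe sets 0 and 4.

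After each probe set's mean was removed, each Q319 array correlated more with its own line than with any other on average (mean r of 0.32 to 0.56 within the line, below 0 with every other line, across probe sets, which are not independent replicates), and in no other line did all 5 arrays do so. Every L43 array correlated more on average with another line (highest mean r of 0.07 to 0.19) than with its own (-0.13 to 0.08). The arrays of L282 and Huangzao4 were mixed. Sequence differences under single probes are argued against only weakly as the whole cause of the distance of Q319. Of 21 genes with a second probe set 16 shifted the same way (76.2%, 95% exact Clopper-Pearson interval 52.8% to 91.8%). Only 3 of these second probe sets were called in the same direction themselves, and 0 in the opposite. The second probe sets shifted less, by a median of 0.36 against 1.07. Whether the probe sets of a gene share sequence was not examined, so part of the signal may still come from probe sequence. RNA breakdown in the Q319 arrays of days 1, 4 and 7, where the ef1a difference was highest, cannot be told apart in full: for 1321 probe sets chosen on these days alone, the shift on days 0 and 2 had the same sign at 94.1% and a median of 75.2% of that on the chosen days, but the lower quartile of the ratio was 47.2%, below the 50% set for excluding it. The day 2 array of Q319, used for comparison, had the lowest array weight of all arrays (0.178) and the lowest mean r within its line (0.32). A lower ratio may also come from that array or from choosing the probe sets on the other days, so the ratio cannot decide. The actin control disagreed with ef1a, as its difference was not raised on the Q319 arrays of days 1, 4 and 7 (2.36, 1.82 and 1.94). A difference in signal scale is argued against, as 95.5% of the probe sets that set Q319 apart were called again in the same direction after quantile normalization. A difference in genotype, which the design names, stays open and untested.

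The cellulose synthase list swung between arrays, from a median deviation of -2.02 in L43 on day 2 to 1.65 in L282 on day 4. Scaling is argued against, since the range over the 20 arrays was 102% of the deposited one after quantile normalization (3.75 against 3.67). RNA breakdown cannot be told apart: the list fell with the 3' minus 5' difference of the ef1a controls with Pearson's r = -0.354 (permutation p = 0.127) and Spearman's rho = -0.436 (permutation p = 0.0561), adjusted p = 0.381 and 0.168 over 3 measures, and r = -0.356 without the 2 farthest arrays. The other 2 measures, the actin difference and the share of zeros, gave r = 0.179 and -0.0319 (adjusted p = 0.676 and 0.894). Without the 2 farthest arrays of each, r was 0.521 and 0.109. Growth stage at sampling may also differ between arrays and was not tested.

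Other splits of the arrays were counted for each result, and each count of shuffles or splits given here includes the real arrangement. For the line effect, 1 of 100 shuffles within days reached the real 2696 (highest other 2286), and for the day effect 1 of 100 within lines reached 2237 (highest other 531), so chance can be excluded for both. The splits of pairs and days regrouped the arrays without regard to shared days and lines. For L282 against L43, Huangzao4 and Q319, 1 of 100 splits reached 110, 238 and 3112 (highest others 53, 2 and 965), and likewise 1 of 100 for L43 and Huangzao4 against Q319 with 2230 and 2309 (highest others 108 and 1), and 1 of 35 splits reached 1795 and 3752 on days 4 and 7 (highest others 2 and 0). The other splits of each pair and day called a median of 0 probe sets, as regrouping across days or lines puts real differences into the error. Rarely reaching the real count therefore shows only that the real grouping stands out from such splits, and does not exclude chance. For L43 against Huangzao4, 3 of 100 reached 214. The highest other there gave 967, which points to a structure of the samples: it set the L43 arrays of days 0, 2 and 4 and the Huangzao4 arrays of days 2 and 4 against the rest. On day 2, 3 of 35 splits reached 499, so chance cannot be excluded by them, and the highest other gave 2580, again a structure, with the day 0 arrays of L282 and L43 and the day 2 arrays of L43 and Huangzao4 on 1 side. On day 1 all 35 splits gave 0. Swaps of 2 lines within days allow 16 arrangements, and swaps of 2 days within lines 8, too few for a share under 0.05. Among them the highest others were 3, 2 and 0 for L282 against L43, Huangzao4 and Q319, 0 for L43 against Huangzao4, 108 and 437 for L43 and Huangzao4 against Q319, and 0 on days 1, 2, 4 and 7.

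Some arrays of different lines or days resembled each other closely after each probe set's mean was removed. The day 0 and day 1 arrays of Q319 correlated at 0.92 and those of Huangzao4 at 0.80, the day 0 arrays of L282 and L43 at 0.73, and the day 1 array of L43 correlated best with the day 0 array of Huangzao4, at 0.70. With no test, 175 and 421 probe sets lay at least 2-fold apart between days 0 and 1 in Q319 and Huangzao4, against 1769 in L282 and 1323 in L43.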
